A study of Mus musculus with 6 samples.

How the data were processed

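The series profiled chromatin of mouse embryonic fibroblasts by chromatin immunoprecipitation and sequencing. Per the labels' protocols, a single EED-knockout clone derived with Cre from floxed cells was transduced to express wild-type EED, EED R302S or EED Y365A. Chromatin was fixed briefly with formaldehyde, cut to mononucleosomes with micrococcal nuclease and precipitated with an antibody against EZH2 or against trimethylated lysine 27 of histone H3 (H3K27me3). The 6 samples form 6 groups of 1 library each, from 3 forms of EED and 2 antibodies. Peak lists of 2 of them were used: EZH2 in the wild-type rescue and H3K27me3 in the R302S rescue. The other 4 samples were not analysed here. The 2 lists come from different antibodies and different EED forms, so those differences cannot be separated, and with 1 library per group no test between conditions was possible and no p-value is given.

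Per the submitters' processing notes, Bowtie 1.0.0, deepTools and the genome build mm9 were used. The peak caller, its thresholds, any input control and any pooling are not given in the sources used here. Each deposited list holds peak positions only, with no height, fold enrichment, score or p-value per peak, and in the H3K27me3 list a name (the submitters called these peaks residual). Read depth is therefore unknown for both libraries. Because the values are positions called by the authors, a weak site missing from a list cannot be told from an unoccupied one.

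In both lists every start was a multiple of 200 bp and every end lay 1 bp short of one, so the ends were taken as the last base of a 200 bp bin counted from 0. Positions are given here in mm9, counted from 1, and widths are multiples of 200 bp. No peaks overlapped within a list. The smallest width was 800 bp in the EZH2 list and 400 bp in the H3K27me3 list, and the smallest gap between neighbouring peaks was 2200 bp and 1200 bp, so the lists follow different joining and size limits and their widths are not on exactly the same footing.

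Peaks were called overlapping when they shared at least 1 bp. Overlaps were computed with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15 and checked against bedtools 2.31.1, which gave the same counts. The overlap was set against 1000 seeded placements of the EZH2 peaks on their own chromosomes, between the first and last peak position of either list. Placements describe these 2 lists and are not a test between conditions. Wilson intervals (95%, scipy 1.17.1) accompany shares of peaks, and intervals of width ratios come from 2000 bootstrap resamples of peaks. Both cover counting error within 1 library only, and neighbouring peaks are not independent. On simulated data of 1206 peaks for this same comparison, all 500 peaks set onto EZH2 sites were recovered, and 1 unrelated list gave 0.817 times the placed overlap. The 500 peaks began at EZH2 peak centres, so their recovery checks the counting only and not the sensitivity to real sites.

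The regions named in the text follow a rule set before the data were examined: the 5 widest peaks of each list, the 5 widest of each list with no peak of the other within 5 kb, and in each list the 5 fixed windows of 100 kb with the most peaks, with ties going to the larger covered length. Alternatives set at the same time were other overlap criteria, joined peaks, the wider 50% of each list, autosomes only and placement near the original site. 2 more were chosen after seeing the data: leaving out windows of 100 kb with 5 or more H3K27me3 peaks, alone or together with sequences that hold no EZH2 peak, and bringing the H3K27me3 list to the smallest gap and width of the EZH2 list, together and each alone. The planned comparisons at gene starts were not made, and no genes are named, because the gene table at hand was of assembly GRCm38 and no mm9 annotation was used here. Figures were drawn with matplotlib 3.10.9.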

Results

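Polycomb repressive complex 2 (PRC2) methylates lysine 27 of histone H3 through its catalytic subunit EZH2, and its subunit EED binds the trimethylated product, which stimulates the enzyme. The series asked how methylation is laid down when this stimulation is impaired, using mouse embryonic fibroblasts that lack their own EED and express a rescue form of it. The data analysed here were the sites of EZH2 in cells rescued with wild-type EED and the sites at which H3K27me3 was called in cells rescued with EED R302S, from 1 library each. The EZH2 list held 3449 peaks covering 11.9 Mb, with a median width of 2400 bp (quartiles 1400 and 4200 bp, range 800 to 47000 bp). The H3K27me3 list held 948 peaks that overlapped an EZH2 peak and 278 that did not. It covered 5.89 Mb, with a median width of 3400 bp (quartiles 1400 and 6400 bp, range 400 to 74400 bp). EZH2 peaks lay on the 19 autosomes and the X chromosome, and 50 of them were on X. H3K27me3 peaks lay on the same chromosomes except for 1 peak on Y and 19 on unplaced sequences. Read depth and per-peak signal were unknown for both libraries, so neither the amount of H3K27me3 nor its change between EED forms could be measured.

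The first comparison asked whether the H3K27me3 peaks called in R302S cells lay at the sites where EZH2 was called with wild-type EED. Most of these peaks did. In the R302S rescue, 948 H3K27me3 peaks overlapped an EZH2 peak of the wild-type rescue and 278 did not, so that 77.3% overlapped (95% Wilson interval 74.9% to 79.6%). EZH2 peaks placed at random on their own chromosomes met 1.30% ± 0.322 of the H3K27me3 peaks (SD over 1000 placements), and none of the placements exceeded 2.53%. The observed overlap was 59.6 times the placed one (57.7 to 61.3 from the interval of the share). Moving each EZH2 peak by 50 kb to 1 Mb, which keeps it in its own neighbourhood, raised the overlap by placement to 2.81% ± 0.457 and lowered the ratio to 27.5. The antibody and the EED form both differed between the lists, and no replicate stood behind either.

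The reverse comparison asked how many EZH2 sites carried a called H3K27me3 peak in R302S cells. These were a minority. Of the 3449 EZH2 peaks, 957 overlapped an H3K27me3 peak, which is 27.7% (95% Wilson interval 26.3% to 29.3%), and 2492 did not. Random placement gave 0.459% ± 0.114 (SD over 1000 placements), and moving the EZH2 peaks by 50 kb to 1 Mb gave 1.04% ± 0.175. The observed share was 60.5 times the first and 26.6 times the second. Because a threshold decides which peaks were listed, the 2492 sites were sites with no called peak, and weaker methylation there could not be assessed. False EZH2 calls among them were not examined either. The H3K27me3 list of the wild-type rescue was not analysed here, so these sites cannot be described as having lost the mark.

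EZH2 sites with H3K27me3 in R302S cells were the wider ones. Their median width was 4200 bp, against 2000 bp for EZH2 sites without it, a ratio of 2.1 (95% bootstrap interval 2.0 to 2.3 over peaks). In the narrowest width class, 800 to 1400 bp, 50 of 863 EZH2 peaks had an H3K27me3 peak (5.79%, interval 4.42% to 7.56%). The share was 14.5% of 885 peaks of 1600 to 2400 bp and 34.6% of 882 peaks of 2600 to 4200 bp. It reached 57.9% (54.5% to 61.2%) of the 819 peaks of 4400 bp or more. Wider peaks meet others more often by chance, but placement gave only 0.333% in the narrowest class and 0.701% in the widest. The ratio of observed to placed overlap was 17.4 in the narrowest class and 82.5 in the widest. Without scores, weak EZH2 calls cannot be told from narrow sites, so whether the trend follows width or strength was not tested. For H3K27me3 peaks the observed share also climbed with width, from 43.5% (38.1% to 49.1%) of 308 peaks of 400 to 1400 bp to 93.4% (90.1% to 95.7%) of 304 peaks of 6600 bp or more. Their ratio to placement was 82.0, 88.6, 68.3 and 37.8 from the narrowest class to the widest. The placed share behind it was 0.531% ± 0.425 in the narrowest class and 2.47% ± 0.845 in the widest (SD over 200 placements). With 93.4% already overlapping, the ratio in the widest class could hardly be higher. Its fall follows the higher placed share and does not mean less overlap of wide H3K27me3 peaks.

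**Figure D1:**
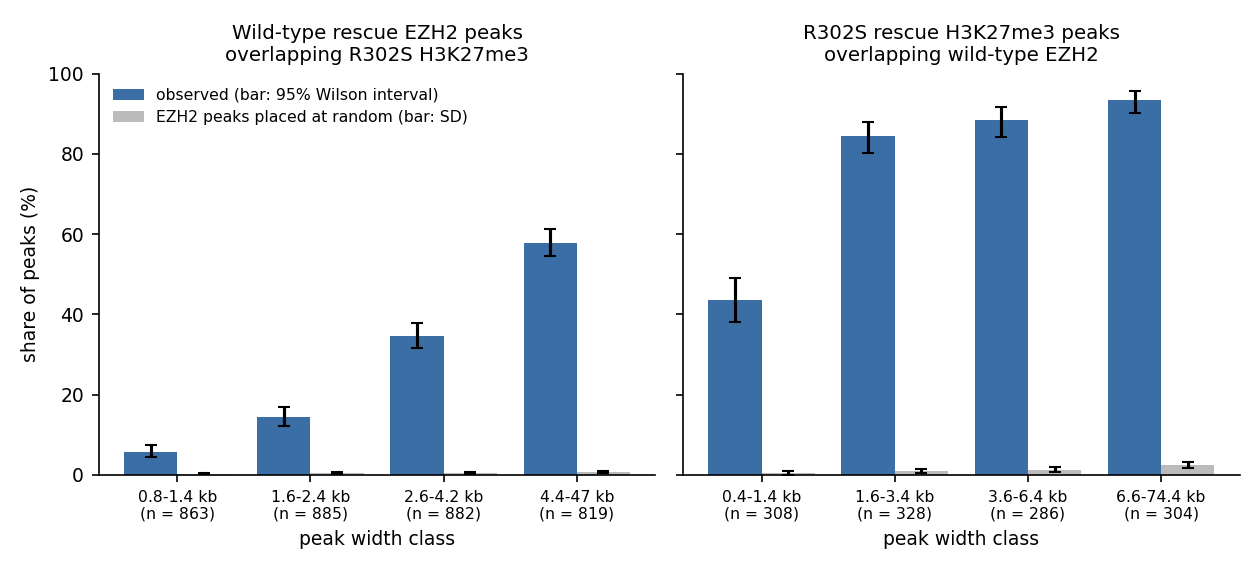
Share of peaks (%) that overlap the other list, by peak width class in kb, for EZH2 peaks of the wild-type rescue (left) and H3K27me3 peaks of the R302S rescue (right). Blue bars are the observed shares with 95% Wilson intervals and grey bars the mean over 200 random placements with SD; the EZH2 share climbs from 5.79% in the narrowest class to 57.9% in the widest.

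The next comparison asked how far the H3K27me3 of R302S cells reached beyond the EZH2 sites. Where both peaks were present, 76.0% of the H3K27me3 length lay inside EZH2 peaks. Over all peaks 4.0 Mb were covered by both lists, which is 68.0% of the H3K27me3 length and 33.6% of the EZH2 length. Of the 1.89 Mb of H3K27me3 outside EZH2 peaks, 1.26 Mb belonged to peaks that overlapped an EZH2 site and 0.624 Mb to peaks that did not. Among the 948 overlapping H3K27me3 peaks, 387 (40.8%) lay wholly inside EZH2 peaks, and the median peak had 90.0% of its length inside (quartiles 68.9% and 100%). In 896 pairs of 1 H3K27me3 peak with 1 EZH2 peak, the median width ratio was 1.0 (quartiles 0.625 and 1.39). H3K27me3 was the wider in 429 pairs, EZH2 in 429 and neither in 38. The H3K27me3 peak extended past its EZH2 peak by a median of 400 bp, both sides summed, and by more than 5 kb in 42 pairs. The centres lay a median of 400 bp apart. These pairs left out 22 H3K27me3 peaks that met 2 or more EZH2 peaks and 16 EZH2 peaks that met 2 or more H3K27me3 peaks. Among those left out was a wide H3K27me3 peak of 35.6 kb on chromosome 11, so the pairs do not cover the reach of such domains. Widths depend on each list's own joining limit, and the antibodies need not give the same profile at one site. The H3K27me3 list of the wild-type rescue was not analysed here, so whether this reach differs from that with wild-type EED is unknown.

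At 4 of the 5 widest EZH2 peaks, R302S cells had H3K27me3. The widest spanned 47.0 kb on chromosome 2 (74492201 to 74539200), of which 57.4% was inside H3K27me3 peaks. On chromosome 19 a peak of 35.4 kb (45199601 to 45235000) was covered to 55.9%, and a peak of 26.8 kb (6490001 to 6516800) to 88.8%. On chromosome 11 a peak of 29.0 kb (98175001 to 98204000) was covered to 98.6%. The exception was a peak of 28.2 kb on chromosome 17 (45661201 to 45689400), whose nearest H3K27me3 peak was 901.6 kb away. The other wide EZH2 peaks with no H3K27me3 peak within 5 kb lay on chromosome 11 (116774201 to 116798000, 23.8 kb), chromosome 15 (102738001 to 102758400, 20.4 kb), chromosome 17 (13368401 to 13386200, 17.8 kb) and chromosome 19 (6414001 to 6430600, 16.6 kb).

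**Figure D2:**
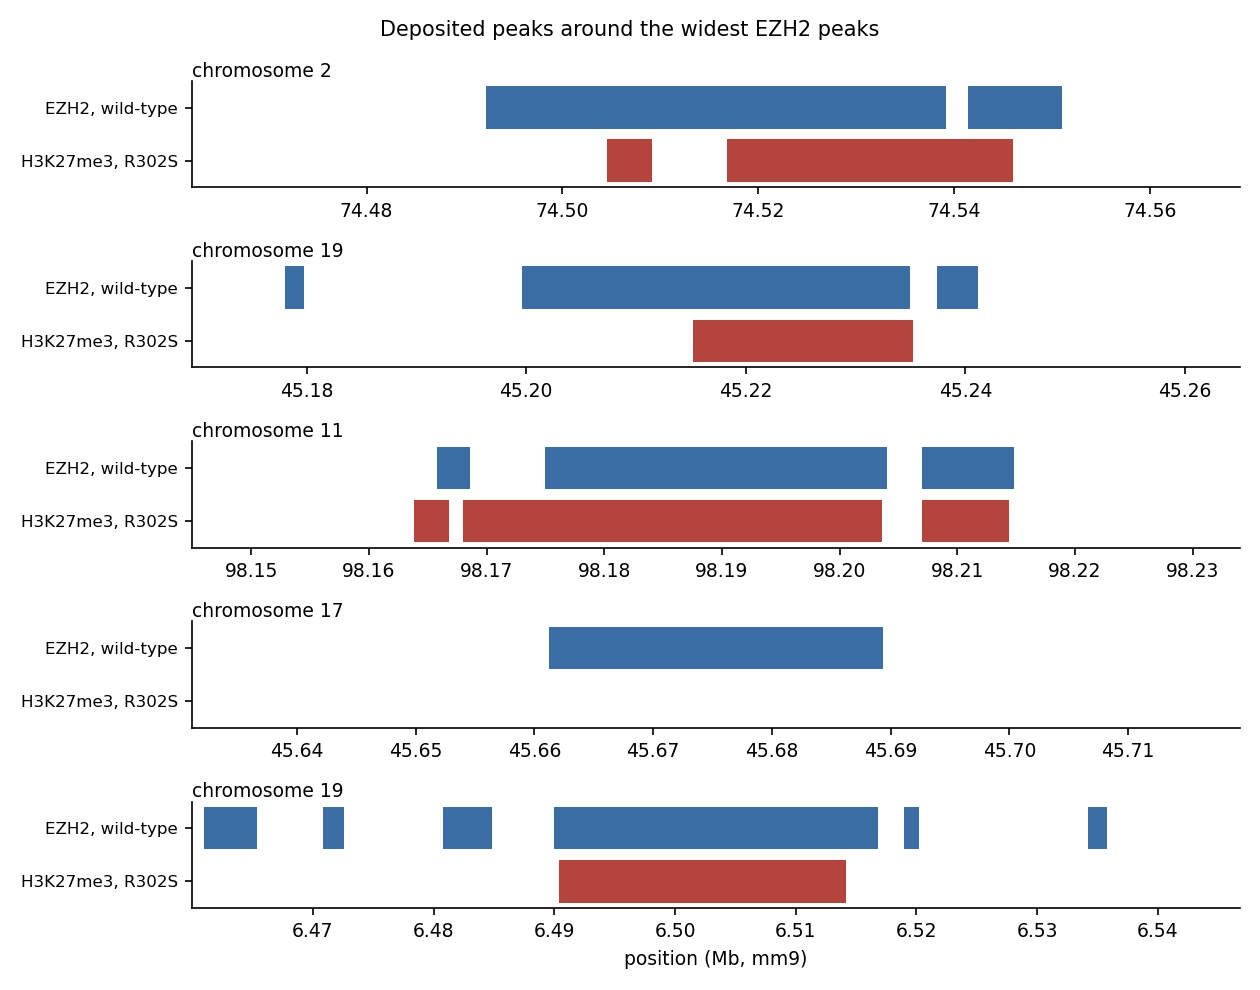
Maps of the 5 widest EZH2 peaks, each with 30 kb on either side; the horizontal axis is the mm9 position in Mb, blue boxes are EZH2 peaks of the wild-type rescue and red boxes H3K27me3 peaks of the R302S rescue. H3K27me3 covers between 55.9% and 98.6% of the peaks on chromosomes 2, 19 and 11, and the 28.2 kb peak on chromosome 17 has none.

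Among the 5 widest H3K27me3 peaks of R302S cells, 4 overlapped EZH2 sites. They lay on chromosome 19 (44804001 to 44842800, 38.8 kb, 79.9% inside EZH2 peaks), chromosome 11 (98168001 to 98203600, 35.6 kb, 82.0%), chromosome 2 (31483201 to 31514800, 31.6 kb, 80.4%) and chromosome 7 (86673601 to 86704800, 31.2 kb, 42.9%). The widest of all, 74.4 kb on chromosome 11 (3025801 to 3100200), did not, although an EZH2 peak lay 3.2 kb away. It was 1 of 2 H3K27me3 peaks in its window of 100 kb, close to the first H3K27me3 peak of that chromosome (from 3001201), and whether its sequence is repeated elsewhere in the genome was not tested.

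The 278 H3K27me3 peaks without an EZH2 peak were narrower than the others, with a median of 800 bp against 4000 bp. Of these, 20 were on sequences with no EZH2 peak at all. The remaining 258 lay a median of 186.0 kb from the nearest EZH2 peak (quartiles 40.5 and 688.8 kb), and 17 of them lay within 5 kb of one. The widest with none within 5 kb were on chromosome 9 (3020001 to 3033000, 13.0 kb), on unplaced sequence of chromosome 8 (674601 to 685600, 11.0 kb), on chromosome 5 (15034801 to 15045200, 10.4 kb), on chromosome 8 (56199201 to 56209200, 10.0 kb) and on sequence with no chromosome (3754601 to 3763000, 8.4 kb). The peak on chromosome 9 was 1 of 4 in its window, next to the first H3K27me3 peak of that chromosome (from 2999801). The genome sequence was not used here, so repeats at these sites were not examined directly.

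Both lists had local clusters, and their 5 densest windows did not coincide. The H3K27me3 windows of 100 kb with the most peaks were 3 adjoining windows of chromosome 5 between 14900001 and 15200000, with 17, 8 and 17 peaks, and 2 windows of chromosome 8, starting at 19700001 and 19900001, with 7 and 11 peaks. Only 1 of these 60 peaks overlapped an EZH2 peak. The densest EZH2 windows held 9 peaks each, on chromosome 17 (from 25600001) and chromosome 12 (from 113600001). Windows with 8 EZH2 peaks lay on chromosome 8 (from 123200001) and chromosome 17 (from 24900001), and one with 7 on chromosome 17 (from 8200001). Of these 41 EZH2 peaks, 1 overlapped H3K27me3.

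The share of EZH2 sites with H3K27me3 in R302S cells differed between chromosomes. It was lowest on chromosome 17, where 40 of 300 EZH2 peaks had it (13.3%, interval 9.95% to 17.6%), followed by chromosome 15 (19.1%, 14.7% to 24.5%) and chromosome 4 (20.2%, 16.4% to 24.7%). It was highest on chromosome 7, where 61 of 128 had it (47.7%, 39.2% to 56.3%). Chromosome 17 also had the most EZH2 peaks per Mb, 3.52, against 0.861 on chromosome 7, while the H3K27me3 list had 0.564 and 0.430 peaks per Mb there. Over all 20 chromosomes the densities of the lists went together, with Spearman rho = 0.86 and Pearson r = 0.71 (0.86 and 0.78 without chromosomes 17 and 19, the farthest from the median). Chromosomes 11 and 19, with 2.52 and 3.12 EZH2 peaks per Mb, had 0.891 and 0.806 H3K27me3 peaks per Mb, whereas chromosomes 4 and 15, with 2.30 and 2.54, had 0.552 and 0.538. Both densities divide by the same span, which by itself pulls them together. The share of EZH2 peaks with H3K27me3 was lower where EZH2 peaks were denser (rho = -0.56 and r = -0.66). With 1 share for all chromosomes, 95% of 1000 simulated draws gave a rho between -0.46 and 0.46, counting error only. The EZH2 count enters both measures, which by itself can lower rho. The draws averaged a rho of 0, so they do not contain that pull and cannot say how much of the relation it makes. Without chromosomes 17 and 19 the values were -0.41 and -0.51, so the relation depended in part on those. These coefficients are across chromosomes of 1 library each, which are not replicates. In the opposite direction, the share of H3K27me3 peaks that overlapped EZH2 ran from 57.4% on chromosome 5 to 90.4% on chromosome 15, with 85.4% on chromosome 17 and 84.4% on chromosome 7. The 5 densest H3K27me3 windows, with 60 peaks of which 1 overlapped EZH2, all lay on chromosomes 5 and 8 (62.5%). They lower the shares of those chromosomes and add to their H3K27me3 densities (0.952 and 0.703 per Mb), and they were left in for the coefficients above.

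**Figure D3:**
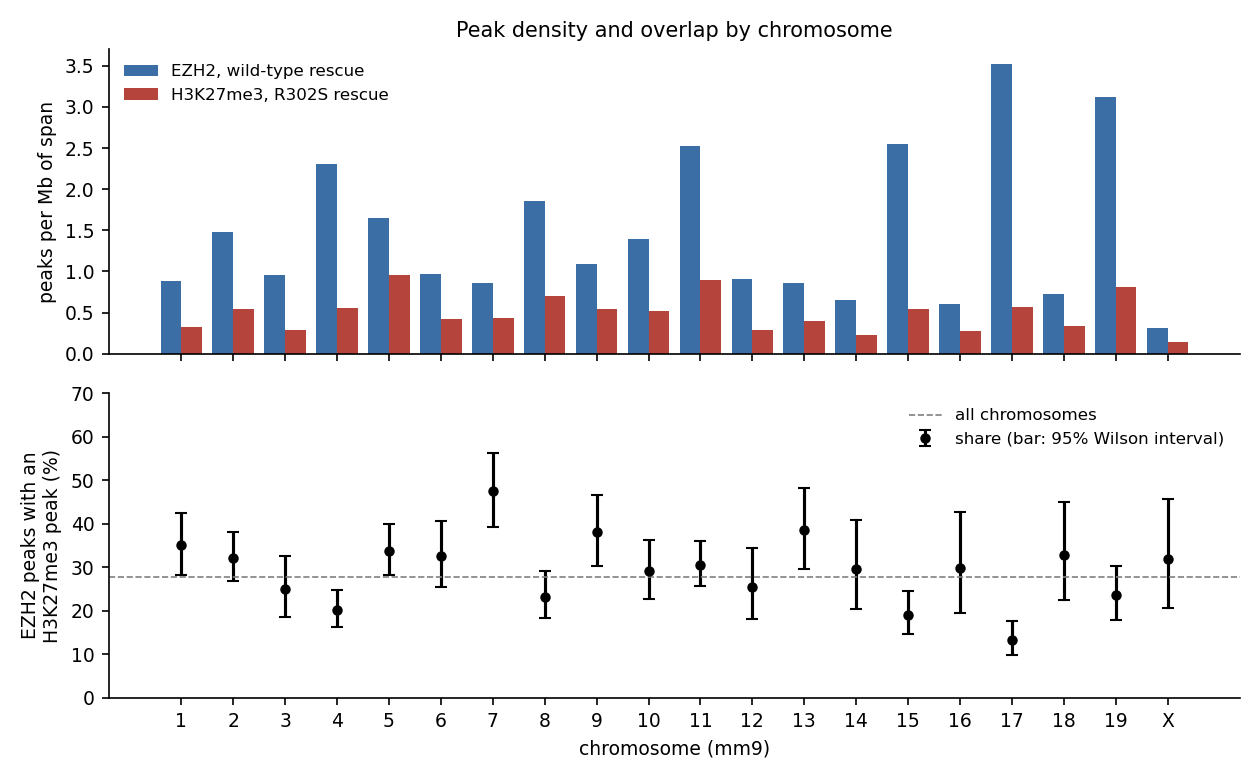
Peaks per Mb of each chromosome's span (top; blue, EZH2 in the wild-type rescue; red, H3K27me3 in the R302S rescue) and the share of EZH2 peaks with an H3K27me3 peak in % (bottom; points with 95% Wilson intervals, dashed line the share of 27.7% over all chromosomes), by mm9 chromosome. Chromosome 17 has the highest EZH2 density, 3.52 per Mb, and the lowest share, 13.3%.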

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

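The overlap stayed far above random placement in the alternatives run. Its ratio to placement, 59.6 as reported, was 27.5 when EZH2 peaks were moved by 50 kb to 1 Mb, which keeps regional density; it was 60.4 without dense windows and unshared sequences and 58.8 with the H3K27me3 list at the gap and width limits of the EZH2 list. The share of H3K27me3 peaks at EZH2 sites (77.3%) fell to 55.3% when at least 50% of both peaks had to be shared. It rose to 84.3% for the wider 50% of each list, 81.7% with peaks within 5 kb joined, 81.2% without dense windows, 82.7% when the 20 peaks on unshared sequences, which cannot overlap, were left out as well, and 86.3% at the matched limits (80.0% with the gap alone matched, 84.5% with the width alone); it stayed inside its interval in the other 4 alternatives. The share of EZH2 peaks with H3K27me3 (27.7%) was 19.7% with 50% of both peaks shared, 29.7% with the nearest peak within 5 kb, 30.7% for the wider 50%, 29.5% with peaks joined, 26.3% at the matched limits and 26.2% with the width alone matched, and stayed inside its interval in the other 6. The width ratio of 2.1 became 2.2 with peaks joined and at the matched limits, and kept its value with 50% of the shorter peak required. The share of H3K27me3 length inside EZH2 peaks, 68.0% as reported, was 70.5% without dense windows and unshared sequences and lay inside its bootstrap interval (65.3% to 70.3%) in the other 4. The alternatives at dense windows (with and without the unshared sequences) and at matched limits (both together and each alone), and all those for the share of length, were chosen after seeing the data. Not run were placement at gene starts, the comparisons at gene starts and a filter on peak score, since no mm9 annotation was used here and the lists carry no score; the wider 50% took the place of a stricter threshold, as planned for that case. No paired analysis was possible because each group had 1 library, and for the same reason none could be left out. With depth unknown, sites below either list's threshold cannot be assessed.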

Other observations

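The tests of edges, repeats, weak calls and peak width were chosen after their results had been seen in part; those of 10 Mb blocks were set before theirs, though after the pattern itself. They describe these 2 lists, and no biological explanation was tested, because antibody and EED form changed together.

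The first pattern was the 278 H3K27me3 peaks of R302S cells with no EZH2 peak. Near misses cannot account for most of them, since only 6.59% of those on shared chromosomes lay within 5 kb of an EZH2 peak. Repeated or unplaced sequence that collects reads may account for part: 29.1% (interval 24.1% to 34.7%) lay in windows with 5 or more H3K27me3 peaks or on sequences without EZH2 peaks, where no peak can match. Dense windows on shared chromosomes held 21.9% (61 peaks), against 0.949% of the matched peaks. The share of 29.1% is no upper limit, because these criteria miss isolated multi-copy sites and do not cover the wide peaks near the starts of chromosomes 9 and 11. Of the 197 peaks elsewhere, 55.3% (48.4% to 62.1%) were 800 bp or narrower, against 8.44% of matched peaks. The limit of 800 bp equals the median width of the unmatched peaks, so their share was largely fixed by that choice. It restates that unmatched peaks were narrower and cannot say how many were weak calls. Weak calls near the threshold stay open, because without scores width is the only measure of strength. Of the 197 peaks, 31 were wider than 3400 bp. H3K27me3 at sites that held EZH2 in R302S cells only is equally open, as that EZH2 library was not analysed here.

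The second pattern was the difference between chromosomes in the share of EZH2 sites with H3K27me3, from 13.3% on chromosome 17 to 47.7% on chromosome 7. Clustering within 10 Mb does not account for it: when whole 10 Mb blocks were reassigned to chromosomes at random, 0 of 1000 reassignments spread the share as widely. Reassignment also breaks any likeness between neighbouring blocks, so clustering over longer stretches stays open. Giving every chromosome the same mix of EZH2 peak widths left the SD between chromosomes at 134% of its first value (10.4 against 7.74 percentage points). Width classes with few peaks add counting error to this SD, as on X (50 peaks, 32.0% before and 46.8% after), so 134% overstates what is left. Differences in width still do not account for the extremes, which stayed apart at 11.7% on chromosome 17 and 55.5% on chromosome 7. A factor acting on whole chromosomes, such as copy number that differs between the 2 rescue lines, could raise EZH2 calls on chromosome 17 with no matching rise in H3K27me3 calls. Both lines came from a single EED-knockout clone, so a copy number difference would have had to arise later. The test of a whole-chromosome factor was undecided. Across 20 chromosomes the share in odd and even 10 Mb blocks correlated with Spearman rho = 0.35 and Pearson r = 0.37. A rho as large came from 77 of 1000 shuffles. Without chromosomes 15 and 17 rho was 0.14 and r 0.17. Odd and even blocks are neighbours, so clustering over longer stretches would also make them alike. Counting error on chromosomes with few peaks lowers rho. Input libraries of the same lines would decide on copy number, but not on other factors that act on whole chromosomes.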
